A study of Mus musculus with 28 samples.

How the data were processed

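Total RNA from frozen lymph-node tumours of lambda-MYC mice on a mixed C57BL/6 and Sv129 background had been labelled and hybridised to 1-colour Affymetrix mouse arrays, 1 tumour per array. The groups, taken from the sample labels, were MYC (n = 5), MYC/AIDKO (n = 5), MYC/BCL6 (n = 12) and MYC/BCL6/AIDKO (n = 6), 28 arrays of separate mice. The design text names 30 mice, 7 of them MYC/AIDKO, and 2 of these were not analysed here. Replicate numbers follow the mouse numbers of the labels within a group.

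The deposited values are probe set intensities (signals) on a linear scale, 1 per probe set and array for 45101 probe sets. The submitters' processing notes name MAS5 and GCOS 1.2. No detection calls were used. The 2% trimmed mean of every array lay between 250.001 and 250.002, so the arrays had been scaled to 1 value, while their medians ranged from 37.8 to 85.5, a ratio of 2.26. The rule set for a ratio above 1.5, scaling to equal trimmed means, therefore changed nothing. Signal over background sets the precision here: the 20th percentile of all values, rounded, was 11, and a change of a gene at that level is compressed by the pseudocount.

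Signals were transformed to log2(signal + 11), where 11 is the 20th percentile of all values. A probe set was tested if at least 5 arrays exceeded 51.7, the median of all values. Of the probe sets, 34945 had 1 gene symbol, and 932 with several symbols, 9160 with none and 64 controls stayed out. Of the 22908 probe sets past the filter with 1 symbol, the one with the highest mean log2 level stood for each of 12717 genes (5802 of which had more than 1). By Entrez identifier, 34741 probe sets were matched to the gene table, which gave chromosomes and positions.

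A linear model with 1 mean per group was fitted over all 28 arrays with limma 3.58.1 (lmFit and eBayes, 24 residual degrees of freedom) in R 4.3.3, with contrasts for the 4 comparisons of 2 groups, the difference of the AIDKO effects and the average AIDKO and BCL6 effects. Genes at a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. The share of variance between 2 groups, summed over all genes, and the difference of mean log2 level of Bcl6 and Myc were tested by exact permutation over all splits of the arrays, the latter two-sided. Fisher's exact test was used for overlaps of calls and for chromosomal position. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest. Arrays were compared with group means by Pearson correlation over genes, the array itself left out of its own group's mean.

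The 22 gene lists (482 genes, 428 on the array) cover germinal centre, naive follicular, immature and precursor, plasma, and marginal zone, B1 and memory B cells, genes described as repressed by BCL6, MYC targets, cell cycle, NF-kB and CD40 response, B cell receptor signalling, MHC class II, interferon response, p53 targets, hypermutation and repair, apoptosis, T cells, myeloid cells, granulocytes and erythroid cells, stroma, and follicular dendritic cells. The 20 of these with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. An estimated correlation and fry were alternatives. Immunoglobulin constant region and sex-linked lists were given as values only. A list of 23 salivary gland markers (14 on the array, no filter) was added after seeing the data and compared between arrays by its mean log2 level. Some genes stand in more than 1 list, and B cell and plasma cell markers are also transcripts of the tumour cells.

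Named genes were Bcl6 and Myc in every comparison, the 10 largest rises and 10 largest falls among called genes of each comparison of 2 groups, the 5 largest each way for the other contrasts, and up to 4 called members of each list by p, with the 2 smallest p given as values where a called list had none. Immunoglobulin genes were kept out of the ranking and described as a group. From these the text names a part. A gene given in a comparison whose rule did not name it, such as Sdc1 in MYC/AIDKO against MYC, was chosen after its values were seen. Of the planned tests, 1 item and the result that needs it are not reported here.

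Groups, tests, lists, filters, the rule for named genes and the alternatives were fixed before the data were examined. The alternatives were quantile normalization, pseudocounts of 5.5 and 22, no filter, a filter at 231.4 (the 75th percentile), all probe sets, the mean over a gene's probe sets, trend and robust variance, array weights, a fit on only the 2 groups compared, mouse number as a block, covariates for mean T cell, myeloid and stroma list level, for the Gapdh 3' to 5' ratio and for Xist, leaving out chromosomes 6 and 12, and leaving out each array in turn. Added after seeing the data were the Actb 3' to 5' ratio as a covariate and leaving out 3 atypical arrays together. On simulated data with 200 changed genes of 12717, the fit recovered 37, 61, 51 and 42% of log2 changes of 1 and 88, 95, 94 and 86% of changes of 2. False calls were 3.10, 4.88, 2.68 and 2.29%. The order is MYC/AIDKO and MYC/BCL6 against MYC, then MYC/BCL6/AIDKO against MYC/BCL6 and MYC/AIDKO. These shares describe the simulation, not the real calls.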

Results

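Lymph-node lymphomas from 28 lambda-MYC transgenic mice were profiled on 1 array each. There were 5 tumours with the MYC transgene alone (MYC) and 5 that also lacked AID, the enzyme of somatic hypermutation and class switching (MYC/AIDKO). A further 12 carried an HA-tagged BCL6 knock-in driven from the immunoglobulin heavy chain locus (MYC/BCL6), and 6 had the knock-in and no AID (MYC/BCL6/AIDKO). Both factors were compared in both backgrounds, and the difference between the 2 AIDKO effects and the average of each effect were tested. Log2 changes are given ± SE from limma over all 28 arrays, and signals as mean ± SD. A count such as 12 of 12 arrays gives the arrays of the first group that lie beyond every array of the second. Folds are on the scale of signal plus 11 and understate changes of genes near the background.

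Bcl6, the knocked-in gene, had a signal of 22.04 ± 26.0 in MYC and 31.1 ± 12.6 in MYC/AIDKO. It had 607.7 ± 689 in MYC/BCL6 and 116.8 ± 53.9 in MYC/BCL6/AIDKO. The MYC tumours had 66, 10, 24.8, 7.1 and 2.3 (replicates 1 to 5), and the MYC/AIDKO tumours 41.4, 11.2, 32.6, 28.1 and 42.2. In MYC/BCL6 replicates 1 to 12 the values were 411.1, 398.5, 255.8, 41, 4.7, 396, 1451.4, 484.1, 241.3, 2248.2, 1279.4 and 81. In MYC/BCL6/AIDKO replicates 1 to 6 they were 110.8, 162, 142.1, 132.4, 12.2 and 141.6. The knock-in with AID present raised Bcl6 by 3.52 log2 units, with 10 of 12 arrays above every MYC array (exact two-sided permutation p = 0.00420). Over the 8 tests of Bcl6 and Myc the adjusted p was 0.0336. Without AID the difference was 1.43, with 5 of 6 arrays above every MYC/AIDKO array (exact permutation p = 0.0325, adjusted p = 0.0866). Bcl6 differed by -1.51 between the knock-in groups (exact permutation p = 0.118, adjusted p = 0.236). Between the groups without it the difference was 0.58 (exact permutation p = 0.270, adjusted p = 0.360). A second Bcl6 probe set differed by 0.35 between MYC/BCL6 and MYC (adjusted p = 0.456). Whether either probe set covers the inserted sequence is not known here.

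Myc had signals of 37.0 ± 19.4 in MYC, 53.4 ± 58.5 in MYC/AIDKO, 34.9 ± 22.8 in MYC/BCL6 and 127.7 ± 78.1 in MYC/BCL6/AIDKO. It was higher in MYC/BCL6/AIDKO than in MYC/BCL6 by 1.43 log2 units, with 5 of 6 arrays above every MYC/BCL6 array (exact permutation p = 0.0101, adjusted p = 0.0405). The adjusted p of limma, 0.0178, became 0.0621 without MYC/BCL6/AIDKO replicate 6. Myc differed by 0.13 between MYC/AIDKO and MYC (exact permutation p = 0.833, adjusted p = 0.833). MYC/BCL6 and MYC differed by -0.16 (exact permutation p = 0.684, adjusted p = 0.782). For MYC/BCL6/AIDKO against MYC/AIDKO the value was 1.14 (exact permutation p = 0.156, adjusted p = 0.249).

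Xist, expressed from the inactive X chromosome, was high in all 5 MYC tumours (5016 to 7131). In MYC/AIDKO only replicate 2 had it (2961, the others at most 15). It was high in MYC/BCL6 replicates 1 to 5 (2599 to 7021), lower in replicate 8 (472.5), and high in MYC/BCL6/AIDKO replicates 3, 4 and 5 (1735 to 3995). The Y-linked gene Eif2s3y had the opposite pattern. By these genes the MYC tumours came from females and the other groups from both sexes.

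RNA integrity and other cells also differed between the groups. The log2 3' to 5' ratio of Actb was 0.81 ± 0.42 in MYC/BCL6 (highest 1.75). It was 0.52 ± 0.22, 0.59 ± 0.20 and 0.44 ± 0.10 in MYC, MYC/AIDKO and MYC/BCL6/AIDKO. The same ratio of Gapdh was 0.26 ± 0.11 in MYC and 0.20 ± 0.18 in MYC/BCL6. It was -0.004 ± 0.23 in MYC/AIDKO and -0.010 ± 0.07 in MYC/BCL6/AIDKO, lower in both groups without AID. T cell markers averaged 7.44 ± 1.08 on the log2 scale in MYC/BCL6/AIDKO and 6.06 to 6.35 in the other groups. Stromal markers averaged 8.95 ± 0.55 in MYC/BCL6 and 7.59 to 7.85 elsewhere. Granulocyte and erythroid markers were high in MYC/AIDKO replicate 5 (10.47) and MYC/BCL6/AIDKO replicates 4 (9.12) and 6 (9.97).

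Over all genes, MYC/BCL6 arrays 1 to 11 lay apart from all other arrays. MYC/BCL6 replicate 12 correlated more closely with the mean of the MYC/BCL6/AIDKO arrays (0.939) than with that of its own group (0.866). MYC/BCL6/AIDKO replicate 5 was closer to MYC/AIDKO (0.964) than to its own group (0.907). MYC/AIDKO replicates 1 and 3 were nearer to the MYC mean. All 5 MYC arrays, 11 of 12 MYC/BCL6 arrays, 5 of 6 MYC/BCL6/AIDKO arrays and 3 of 5 MYC/AIDKO arrays were nearest to their own group. MYC/AIDKO replicate 1 also had a median signal of 85.5, against at most 60.0 in any other array.

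**Figure D1:**
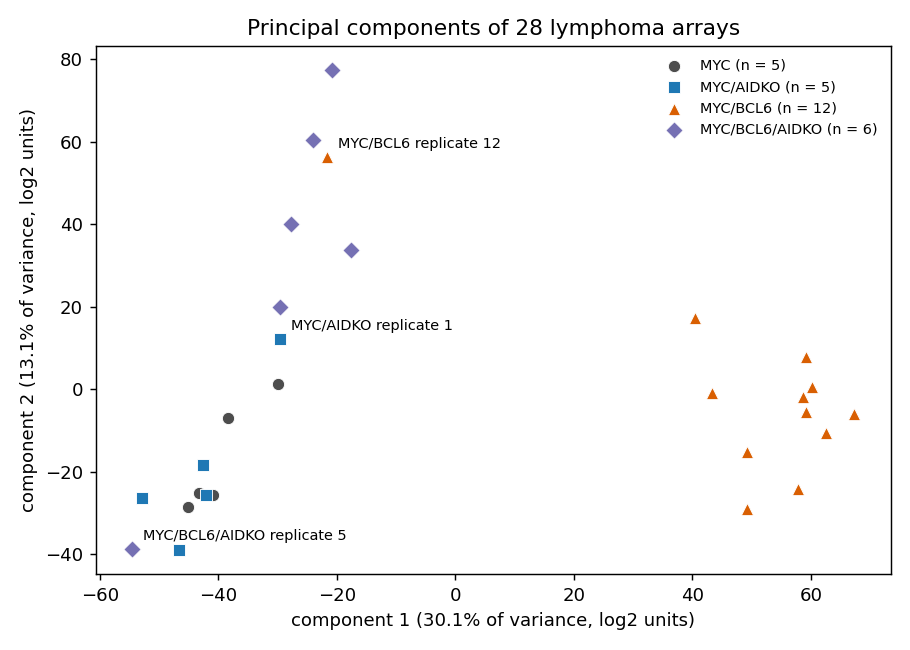
Each point is 1 array placed by its scores on the first and second principal components of log2(signal + 11) over 12717 genes (axes in score units; 30.1% and 13.1% of the variance), coloured by group. MYC/BCL6 arrays 1 to 11 lie on the positive side of component 1 and every other array, MYC/BCL6 replicate 12 included, on the negative side.

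The BCL6 knock-in with AID present went with high plasma cell genes and low B cell identity genes. Sdc1, the syndecan of the plasma cell surface, rose 23.6-fold (log2 change 4.56 ± 0.59, adjusted p = 3.58e-06, signal 4045 ± 1276 against 181 ± 119.6, 12 of 12 arrays). Xbp1, the transcription factor of secretory cells, rose 13.1-fold (log2 change 3.71 ± 0.38, adjusted p = 3.84e-07, 12 of 12 arrays), and Prdm1, which encodes Blimp-1, 10.1-fold (log2 change 3.33 ± 0.46, adjusted p = 6.68e-06, 11 of 12 arrays). Ell2, an elongation factor used for secretory immunoglobulin mRNA, rose 50.5-fold (log2 change 5.66 ± 0.57, adjusted p = 3.84e-07, 12 of 12 arrays). Cd79a, a signalling chain of the B cell receptor, was 41.3-fold lower (log2 change -5.37 ± 0.85, adjusted p = 3.48e-05, 11 of 12 arrays). The Ets factor Spib was 24.9-fold lower (log2 change -4.64 ± 0.71, adjusted p = 2.52e-05, 12 of 12 arrays). These are differences between 12 and 5 tumours.

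In all, 3452 of 12717 genes differed between MYC/BCL6 and MYC, 1879 higher and 1573 lower. Group accounted for 32.6% of the variance (exact permutation p = 0.000162, the smallest that 6188 splits can give). The largest rise was that of Pgam2 (log2 change 6.88 ± 0.83, 11 of 12 arrays). Epcam (5.68 ± 0.72), Ell2, Mamdc2 (5.66 ± 0.67) and the plasma cell poly(A) polymerase gene Tent5c (5.49 ± 0.96) followed. Gabra4 (5.33 ± 0.63), Nbea (5.08 ± 0.80), the cyclin D2 gene Ccnd2 (4.91 ± 0.53), Phlda1 (4.84 ± 0.64) and Dsp (4.83 ± 0.72) were next. Their adjusted p ran from 3.84e-07 (Ell2) to 0.000106 (Tent5c). Falls beside those of Cd79a and Spib were largest for Vpreb3 (-5.06 ± 0.73), Serpinb1a (-4.91 ± 0.61) and the transcriptional repressor Bach2 (-4.85 ± 0.69). Tnfrsf19 (-4.62 ± 0.48), B3gnt5 (-4.14 ± 0.72) and Ms4a1, which encodes CD20 (-3.98 ± 1.07, adjusted p = 0.00623), fell as well. So did the adaptor Bank1 (-3.76 ± 0.60) and Trib2 (-3.75 ± 0.51).

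MYC/BCL6 replicate 12 was the exception in its group. Its Sdc1 signal was 679.2 against a group median of 4176, and its Xbp1 signal 3734 against 22432. Its Spib signal was 1153 against a median of 52.25, and only replicate 10 was as high (1285).

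Plasma cell genes rose (median 2.28, camera adjusted p = 5.69e-09, adjusted p = 0.135 with an estimated correlation). Among 20 members, 14 rose, 0 fell and 6 did not pass (14 and 0 adjusted over the list alone). Tnfrsf17, the receptor BCMA (3.50 ± 0.56), and Edem1, of endoplasmic reticulum-associated degradation (3.09 ± 0.34), were among them. B cell receptor signalling genes fell (median -0.83, camera adjusted p = 0.000118, adjusted p = 0.287 with an estimated correlation). Among 22 members, 2 rose, 10 fell and 10 did not pass (2 and 13 adjusted over the list alone). The inhibitory coreceptor Cd22 (-3.20 ± 0.48) and Vav2 (-1.68 ± 0.25) fell, while the adaptor Blnk rose (1.38 ± 0.20). Immature B cell genes fell (median -1.81, camera adjusted p = 0.00484, adjusted p = 0.287 with an estimated correlation). Among 16 members, 1 rose, 8 fell and 7 did not pass (1 and 9 adjusted over the list alone). Myb had -2.63 ± 0.39. Naive B cell genes fell (median -0.96, camera adjusted p = 0.00498, adjusted p = 0.413 with an estimated correlation). Among 16 members, 1 rose, 6 fell and 9 did not pass (1 and 6 adjusted over the list alone). Klf2 (-2.69 ± 0.54), the homing receptor Ccr7 (-3.11 ± 0.64) and Foxp1 (-1.24 ± 0.21) fell.

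Targets of p53 rose (median 0.63, camera adjusted p = 0.00386, adjusted p = 0.349 with an estimated correlation). Among 22 members, 8 rose, 1 fell and 13 did not pass (10 and 1 adjusted over the list alone). Trp53inp1 (2.40 ± 0.44), Phlda3 (1.79 ± 0.26) and Btg2 (1.94 ± 0.30) rose. Stromal and vascular genes rose (median 1.28, camera adjusted p = 0.000118, adjusted p = 0.359 with an estimated correlation). Among 23 members, 12 rose, 0 fell and 11 did not pass (15 and 0 adjusted over the list alone). Lum (1.74 ± 0.43), Col4a1 (1.54 ± 0.36) and Pdgfrb (1.64 ± 0.38) were among them. Srm, a MYC target of polyamine synthesis, rose (0.98 ± 0.22) and the mitotic kinesin Kif11 fell (-0.79 ± 0.20). Across all comparisons, no list passed when camera estimated the correlation between genes instead of presetting it at 0.01. The PValue of fry tests whether a list's genes move on balance in 1 direction and compares them with no other genes. By fry, all 6 lists called here passed, as did all 9 called for MYC/BCL6/AIDKO against MYC/BCL6. Elsewhere fry passed 4 of 8 called lists (MYC/BCL6/AIDKO against MYC/AIDKO), 5 of 7 (difference of AIDKO effects), 6 of 9 (average AIDKO effect) and 7 of 8 (average BCL6 effect).

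No other list passed for MYC/BCL6 against MYC. Genes described as repressed by BCL6 went both ways (6 rose, 3 fell and 13 did not pass, median 0.03, camera adjusted p = 0.539). Germinal centre genes did too (5 rose, 5 fell and 10 did not pass (5 and 5 adjusted over the list alone), median -0.06, camera adjusted p = 0.539). Medians and camera adjusted p were -0.22 and 0.0686 for cell cycle, 0.51 and 0.0765 for interferon response, and -0.63 and 0.0950 for MHC class II. They were -0.06 and 0.210 for hypermutation and repair, 0.08 and 0.367 for MYC targets, and 0.29 and 0.597 for marginal zone, B1 and memory genes. For other cells they were 0.88 and 0.332 (follicular dendritic), 0.33 and 0.539 (myeloid), -0.28 and 0.598 (granulocyte and erythroid) and 0.33 and 0.704 (T cell). Median and mean had opposite signs for NF-kB response (median -0.02, mean 0.14, camera adjusted p = 0.704) and apoptosis (median -0.12, mean 0.04, camera adjusted p = 0.704).

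With the T cell, myeloid and stroma admixed-cell scores as covariates, 1490 genes differed between MYC/BCL6 and MYC, 806 higher and 684 lower. The plasma cell list then had a median of 1.63 (adjusted p = 1.56e-07) and p53 targets 0.35 (adjusted p = 0.0306). The stroma list had 0.04 (adjusted p = 0.968). Of the named genes, 67 of 80 calls held whichever array was left out. Bst2 (1.75 ± 0.52) lost its call without MYC replicate 2 (adjusted p = 0.0552) or 3 (adjusted p = 0.0525). Cd2 (-2.46 ± 0.85) lost it without MYC replicate 1 (adjusted p = 0.0598), 3 (0.0653) or 4 (0.0894). Bcl3 (1.65 ± 0.59) lost it without any of 7 arrays (up to adjusted p = 0.180).

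**Figure D2:**
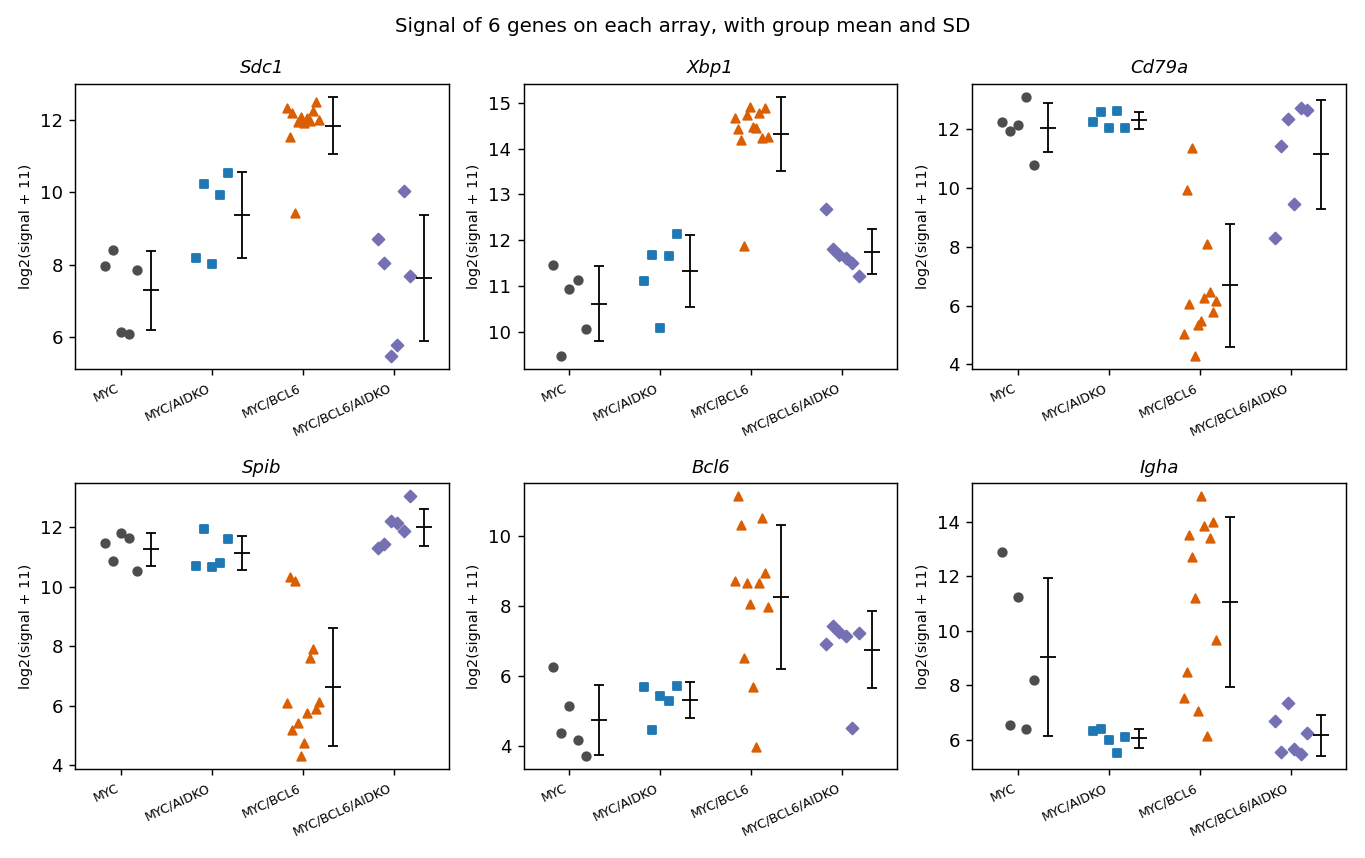
Log2(signal + 11) of Sdc1, Xbp1, Cd79a, Spib, Bcl6 and Igha in each of 28 arrays by group, with the group mean and SD. Sdc1 lies at 679.2 to 5791 in signal in MYC/BCL6 and 57.4 to 331.2 in MYC, and Spib at 8.8 to 1285 against 1458 to 3565.

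Several of these genes differed the other way between MYC/BCL6/AIDKO and MYC/BCL6. Both comparisons use the same 12 MYC/BCL6 arrays with opposite sign, so they are not independent. In MYC/BCL6/AIDKO Spib was 41.8-fold higher than in MYC/BCL6 (log2 change 5.38 ± 0.67, adjusted p = 5.87e-06, signal 4466 ± 2143 against 261 ± 453, 6 of 6 arrays). Cd79a was 22.2-fold higher (log2 change 4.47 ± 0.79, adjusted p = 0.000187, 4 of 6 arrays). Sdc1 was 18.7-fold lower (log2 change -4.22 ± 0.55, adjusted p = 9.23e-06, 5 of 6 arrays) and Tnfrsf17 24.8-fold lower (log2 change -4.63 ± 0.53, adjusted p = 2.75e-06, 5 of 6 arrays). Xbp1 fell by 2.57 on the log2 scale (adjusted p = 1.91e-05, 5 of 6 arrays). These are differences between 6 and 12 tumours.

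There were 3357 genes that differed between MYC/BCL6/AIDKO and MYC/BCL6, 1777 higher and 1580 lower. Group accounted for 27.7% of the variance (exact permutation p = 0.000215, 18564 splits). Rises beside Spib and Cd79a, apart from genes high in few tumours (Bpifa2, 2310057J18Rik, Smr3a and Pip), were largest for Cyb561a3 (5.07 ± 0.75), Ly6d (4.56 ± 0.64), Napsa (4.44 ± 0.62) and Lsp1 (4.42 ± 0.63). Falls were largest for Pgam2 (-5.95 ± 0.78, 61.8-fold), Mamdc2 (-5.18 ± 0.63), Gpm6a (-4.88 ± 0.61) and Gabra4 (-4.82 ± 0.59). The arginase gene Arg1 (-4.72 ± 0.76), Nbea (-4.57 ± 0.75), Spag6 (-4.47 ± 0.49) and Mgarp (-3.93 ± 0.60) fell as well. Ms4a1 (3.96 ± 1.00), Bach2 (3.77 ± 0.65) and Foxp1 (1.15 ± 0.20) rose. Ccnd2 (-3.87 ± 0.50) and Prdm1 (-1.79 ± 0.43) fell.

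The largest rises also include a group of genes high in the same few tumours, salivary protein genes among them. Bpifa2 (5.56 ± 1.29, adjusted p = 0.00219), 2310057J18Rik (4.57 ± 1.10, adjusted p = 0.00314), Smr3a (4.55 ± 1.19) and Pip (4.48 ± 1.14) were higher in MYC/BCL6/AIDKO. Bpifa2 reached 13591, 15538 and 31960 in MYC/BCL6/AIDKO replicates 2, 3 and 4, and 21355 in MYC replicate 1. It was 734.3 in MYC/BCL6/AIDKO replicate 1 and at most 53.6 in the remaining arrays. Smr3a had 235.3, 90.7, 6526 and 21698 in MYC/BCL6/AIDKO replicates 1 to 4 and 9756 in MYC replicate 1.

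MHC class II genes rose (median 2.29, camera adjusted p = 9.90e-07, adjusted p = 0.278 with an estimated correlation). Among 14 members, 10 rose, 0 fell and 4 did not pass (12 and 0 adjusted over the list alone). H2-Ob (3.96 ± 0.66), H2-Ab1 (2.99 ± 0.55), H2-DMa (2.66 ± 0.51) and their transactivator Ciita (1.85 ± 0.34) rose. Genes of B cell receptor signalling rose (median 1.21, camera adjusted p = 7.78e-08, adjusted p = 0.135 with an estimated correlation). Among 22 members, 16 rose, 2 fell and 4 did not pass (17 and 2 adjusted over the list alone). Cd22 (3.47 ± 0.45) and Vav2 (1.76 ± 0.24) were higher. Naive B cell genes rose (median 1.28, camera adjusted p = 1.23e-05, adjusted p = 0.185 with an estimated correlation). Among 16 members, 8 rose, 0 fell and 8 did not pass (11 and 0 adjusted over the list alone). Ccr7 (3.70 ± 0.60) and Klf2 (2.96 ± 0.50) were among them. NF-kB response genes rose (median 0.88, camera adjusted p = 0.00277, adjusted p = 0.520 with an estimated correlation). Among 21 members, 10 rose, 1 fell and 10 did not pass (10 and 1 adjusted over the list alone). Nfkbie (2.80 ± 0.53) and Cd83 (2.51 ± 0.61) were up and Il10 (-2.48 ± 0.49) down.

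T cell genes rose (median 0.83, camera adjusted p = 0.0172, adjusted p = 0.557 with an estimated correlation). Among 17 members, 3 rose, 0 fell and 14 did not pass (3 and 0 adjusted over the list alone). Cd2 (2.81 ± 0.80) and Cd4 (2.92 ± 0.91) rose. The call of this list ended without MYC/BCL6/AIDKO replicate 1 (adjusted p = 0.0760) or 4 (adjusted p = 0.0791). Plasma cell genes fell (median -1.65, camera adjusted p = 1.36e-07, adjusted p = 0.135 with an estimated correlation). Among 20 members, 1 rose, 12 fell and 7 did not pass (1 and 13 adjusted over the list alone). Edem1 had -2.90 ± 0.32, adjusted p = 1.87e-06. Stromal genes fell (median -1.15, camera adjusted p = 1.01e-05, adjusted p = 0.278 with an estimated correlation). Among 23 members, 0 rose, 13 fell and 10 did not pass (0 and 13 adjusted over the list alone). Lum (-2.81 ± 0.40) and Col3a1 (-2.58 ± 0.41) fell. MYC targets fell (median -0.30, camera adjusted p = 0.000209, adjusted p = 0.418 with an estimated correlation). Among 30 members, 0 rose, 9 fell and 21 did not pass (0 and 10 adjusted over the list alone). Srm (-0.98 ± 0.20, adjusted p = 0.000813) and the nucleotide kinase Nme1 (-0.95 ± 0.20, adjusted p = 0.00120) fell. The Myc probe set was higher in this comparison, but its low signals argue against it reading the MYC transgene. Which sequence it covers is not known here. Targets of p53 fell (median -0.48, camera adjusted p = 0.00614, adjusted p = 0.335 with an estimated correlation). Among 22 members, 1 rose, 8 fell and 13 did not pass (1 and 9 adjusted over the list alone). Trp53inp1 (-3.18 ± 0.41) and Phlda3 (-1.35 ± 0.24) fell.

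Other lists did not pass for MYC/BCL6/AIDKO against MYC/BCL6. Medians and camera adjusted p were 0.63 and 0.204 for marginal zone, B1 and memory, 0.79 and 0.283 for immature and 0.66 and 0.313 for germinal centre genes. They were 0.65 and 0.283 for granulocyte and erythroid genes, 0.33 and 0.287 for apoptosis and -0.02 and 0.307 for cell cycle. Interferon response had 0.17 and 0.738, and hypermutation and repair 0.03 and 0.821. Signs differed for genes described as repressed by BCL6 (median 0.23, mean -0.06, camera adjusted p = 0.821), myeloid genes (median -0.01, mean 0.04, camera adjusted p = 0.831) and follicular dendritic cell genes (median 0.07, mean 0.13, camera adjusted p = 0.821, test down).

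The count for this comparison changed with covariates that themselves differ between the groups. With the admixed-cell scores as covariates 76 genes differed (45 higher, 31 lower). With the Gapdh 3' to 5' ratio 2226 did, and with that of Actb 1971. Sdc1, Edem1, Cd22, Ccnd2, Gpm6a and Spag6 were among the named genes that still passed with the scores. The medians were then -1.19 (adjusted p = 5.03e-06) for plasma cell, 1.02 (adjusted p = 5.92e-06) for B cell receptor signalling and 0.88 (adjusted p = 0.00957) for MHC class II genes. They were -0.09 (adjusted p = 0.369) for p53 targets and, as lists in the scores, -0.07 for T cell and 0.16 for stroma genes. Of 85 calls of named genes, 74 held whichever array was left out. Cd4 lost its call without MYC/BCL6/AIDKO replicate 1 (adjusted p = 0.0868), 3 (0.0503) or 4 (0.0501). Vpreb3 (2.14 ± 0.68) lost its call without replicate 5 (adjusted p = 0.0929), and Myb (1.10 ± 0.37) without replicate 5 (adjusted p = 0.118) or 6 (adjusted p = 0.0685).

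In tumours without AID, 62 genes differed with the knock-in, or 847 when MYC/BCL6/AIDKO replicate 5 was left out. Cd93, a receptor of immature B cells, was 6.48-fold lower in MYC/BCL6/AIDKO than in MYC/AIDKO (log2 change -2.70 ± 0.49, adjusted p = 0.0159, 6 of 6 arrays). Vpreb3, an immature B cell gene, was 16.8-fold lower (log2 change -4.07 ± 0.83, adjusted p = 0.0249, 5 of 6 arrays) and the protease inhibitor gene Slpi 25.9-fold lower (log2 change -4.69 ± 0.96, adjusted p = 0.0256, 6 of 6 arrays). Abr rose 5.24-fold (log2 change 2.39 ± 0.35, adjusted p = 0.00347, 6 of 6 arrays). The groups hold 6 and 5 tumours.

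Of the 62 genes, 49 were higher and 13 lower. Group accounted for 17.4% of the variance (exact permutation p = 0.0368, 462 splits). The largest rises were those of Timd2 (3.38 ± 0.70), Rras2 (3.20 ± 0.62), Rab11fip4 (2.98 ± 0.65) and Bmyc (2.93 ± 0.65). Cyp27a1 (2.70 ± 0.53), Shtn1 (2.65 ± 0.57), Zbtb20 (2.53 ± 0.51), Clec2i (2.46 ± 0.48) and Bcl2l14 (2.34 ± 0.54, adjusted p = 0.0414) followed. The peptide transporter Tap1 rose by 1.72 (adjusted p = 0.0378). Emid1 (-4.07 ± 0.74), Lgr5 (-3.40 ± 0.69), Capsl (-3.19 ± 0.61) and Chchd10 (-2.20 ± 0.39) fell. So did the transcription factor Myb (adjusted p = 0.0364), Tspoap1 (-1.79 ± 0.41) and Fam50b (-1.35 ± 0.32, adjusted p = 0.0492).

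Of 20 lists 8 passed, mostly with few members passing singly. NF-kB response genes were higher (median 0.87, camera adjusted p = 2.93e-06, adjusted p = 0.393 with an estimated correlation). Among 21 members, 0 rose, 0 fell and 21 did not pass (8 and 0 adjusted over the list alone). MHC class II genes were higher (median 1.56, camera adjusted p = 2.93e-06, adjusted p = 0.393 with an estimated correlation). Among 14 members, 0 rose, 0 fell and 14 did not pass (11 and 0 adjusted over the list alone). Interferon response genes were higher (median 0.97, camera adjusted p = 2.93e-06, adjusted p = 0.428 with an estimated correlation). Among 22 members, 1 rose, 0 fell and 21 did not pass (6 and 0 adjusted over the list alone). T cell genes were higher (median 1.34, camera adjusted p = 0.00280, adjusted p = 0.430 with an estimated correlation). Among 17 members, 0 rose, 0 fell and 17 did not pass (5 and 0 adjusted over the list alone). Bcl3 (2.33 ± 0.67, adjusted p = 0.0906), H2-Ab1 (2.06 ± 0.66, adjusted p = 0.129), H2-DMa (1.95, adjusted p = 0.121) and Gzmk (2.48, adjusted p = 0.0887) did not pass.

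Marginal zone, B1 and memory genes were higher (median 0.47, camera adjusted p = 0.00280, adjusted p = 0.393 with an estimated correlation). Among 19 members, 1 rose, 0 fell and 18 did not pass (1 and 0 adjusted over the list alone). Naive B cell genes were higher (median 0.65, camera adjusted p = 0.0193, adjusted p = 0.430 with an estimated correlation). Among 16 members, 0 rose, 0 fell and 16 did not pass (2 and 0 adjusted over the list alone). Immature B cell genes were lower (median -0.99, camera adjusted p = 0.000570, adjusted p = 0.354 with an estimated correlation). Among 16 members, 0 rose, 3 fell and 13 did not pass (1 and 6 adjusted over the list alone). Cell cycle genes were lower (median -0.18, camera adjusted p = 0.000998, adjusted p = 0.477 with an estimated correlation). Among 27 members, 0 rose, 0 fell and 27 did not pass (0 and 1 adjusted over the list alone). Il4ra (1.38, adjusted p = 0.0603), Itgb7 (2.52, adjusted p = 0.112) and Ccne2 (-1.19, adjusted p = 0.0790) did not pass. The naive call ended without MYC/AIDKO replicate 4 (adjusted p = 0.0898) or MYC/BCL6/AIDKO replicate 3 (adjusted p = 0.0817). The cell cycle call ended without MYC/BCL6/AIDKO replicate 1 (adjusted p = 0.127). By fry the interferon response (adjusted p = 0.109), T cell (0.117), naive (0.117) and cell cycle lists (0.319) did not pass.

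With the admixed-cell scores as covariates, some of these lists no longer passed. T cell genes, part of the scores, had 0.00. Interferon response had 0.30 (adjusted p = 0.105) and naive genes 0.18 (adjusted p = 0.699). Marginal zone, B1 and memory genes had 0.14 (adjusted p = 0.198) and cell cycle genes -0.12 (adjusted p = 0.108). Granulocyte and erythroid genes newly passed with -0.73 (adjusted p = 0.0482). NF-kB response kept 0.55 (adjusted p = 0.00309), MHC class II 0.69 (adjusted p = 0.00540) and immature B cell genes -0.74 (adjusted p = 3.61e-05). Only 5 genes passed with the scores, Abr, Cd93, Chchd10 and Emid1 among them.

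The remaining lists did not pass for MYC/BCL6/AIDKO against MYC/AIDKO. Genes described as repressed by BCL6 had median 0.33, camera adjusted p = 0.0530. Other medians and camera adjusted p were 0.38 and 0.588 for plasma cell, 0.09 and 0.701 for B cell receptor signalling and 0.10 and 0.588 for germinal centre genes. MYC targets had -0.08 and 0.317, apoptosis 0.36 and 0.160, and myeloid genes 0.30 and 0.121. Stroma had 0.16 and 0.609, granulocyte and erythroid genes -0.24 and 0.269, and follicular dendritic cell genes 0.55 and 0.588. For p53 targets (median 0.10, mean 0.04, camera adjusted p = 0.968) the test leaned down, and for hypermutation and repair (median 0.04, mean -0.09, camera adjusted p = 0.588) median and mean differed in sign.

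The gene count without AID rests on the model and on single arrays. A fit on the 2 groups alone gave 0 genes, mouse number as a block 22 and array weights 1153. The count was 847 without MYC/BCL6/AIDKO replicate 5, 137 without MYC/AIDKO replicate 1 and 111 without MYC/BCL6 replicate 12. It was 2, 18, 4 and 6 without MYC/BCL6/AIDKO replicates 1, 2, 3 and 4, and 4, 19 and 5 without MYC/AIDKO replicates 2, 4 and 5. Among the named genes, 21 of 22 calls ended without MYC/AIDKO replicate 2 (Cd93, Chchd10 and Emid1 at adjusted p = 0.0522). The call of Abr alone held whichever array was left out.

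**Figure D3:**
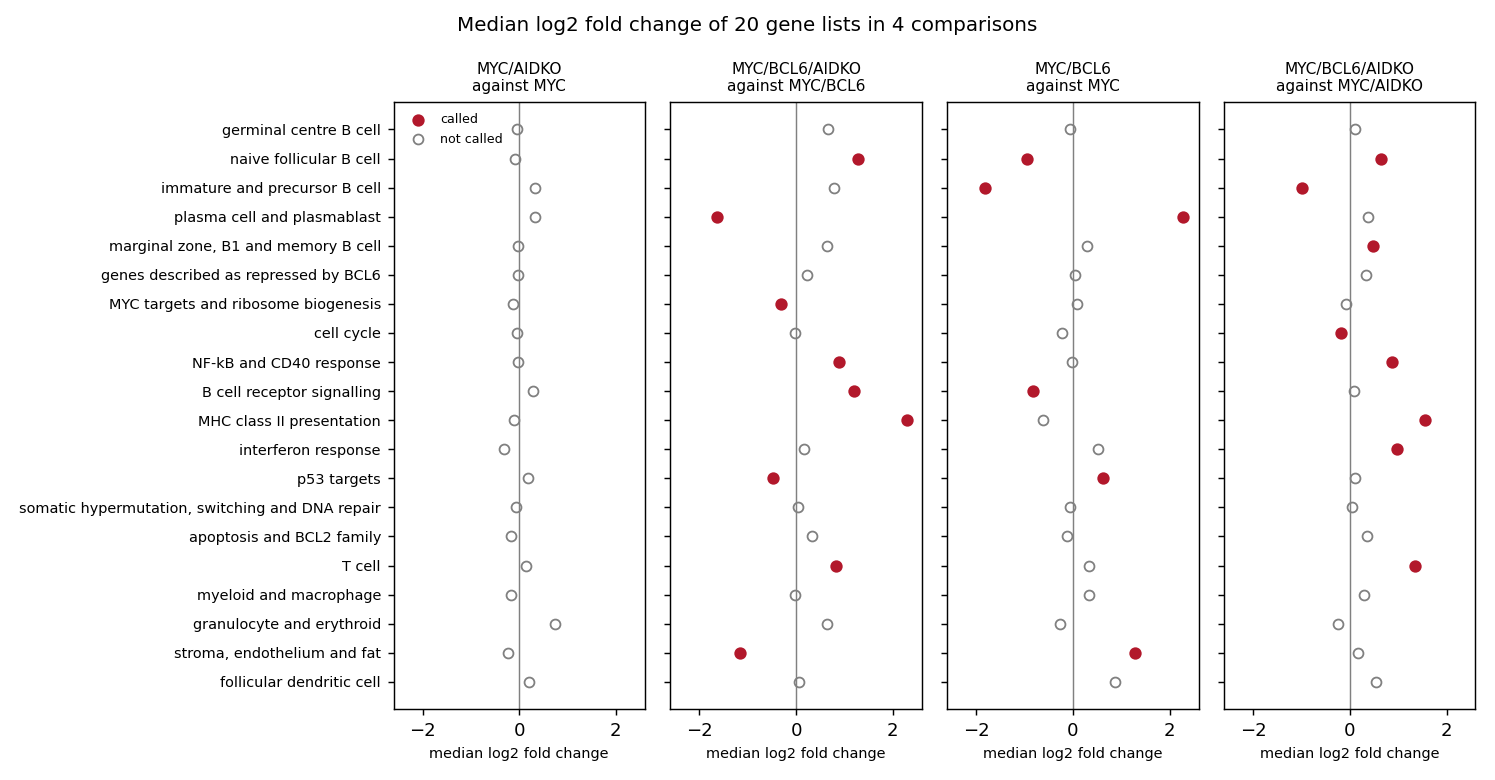
Median log2 change of each of 20 gene lists in the 4 comparisons of 2 groups, with filled points where camera passed at the preset correlation. The plasma cell list lies at 2.28 for MYC/BCL6 against MYC and at -1.65 for MYC/BCL6/AIDKO against MYC/BCL6.

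In tumours without the knock-in, loss of AID went with changes in 10 genes. Cryl1 was 3.30-fold lower in MYC/AIDKO than in MYC (log2 change -1.72 ± 0.29, adjusted p = 0.0117, signal 109 ± 69.5 against 345 ± 47.2, 5 of 5 arrays). Ehhadh, of peroxisomal fatty acid oxidation, was 3.26-fold higher (log2 change 1.71 ± 0.29, adjusted p = 0.0117, signal 46.9 ± 15.7 against 6.64 ± 4.42, 5 of 5 arrays). Rif1, a gene of DNA repair in class switching, fell by 1.27 on the log2 scale (adjusted p = 0.0442, 5 of 5 arrays). Atf7ip (1.35 ± 0.24, adjusted p = 0.0163) and Tmem39b (1.09 ± 0.21, adjusted p = 0.0426) rose. Zdhhc21 (-1.09 ± 0.17, adjusted p = 0.0113), Snx6 (-1.20 ± 0.22, adjusted p = 0.0174) and G3bp2 (-1.01 ± 0.18, adjusted p = 0.0163) fell. So did Eef1akmt1 (-1.48 ± 0.30, adjusted p = 0.0442) and Mir1949 (-1.54 ± 0.31, adjusted p = 0.0496). Each gene had all 5 MYC/AIDKO arrays beyond every MYC array except Eef1akmt1, with 4 of 5.

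Group accounted for 14.9% of the variance between MYC/AIDKO and MYC (exact permutation p = 0.0635, the smallest possible being 0.00794). An unadjusted limma p under 0.05 was found for 1287 genes. Some genes that were high in MYC/BCL6 had positive values without passing: Sdc1 (2.09 ± 0.70, adjusted p = 0.256) and Hnrnpll (3.00 ± 0.76, adjusted p = 0.120). Slpi had 3.62 ± 1.00 (adjusted p = 0.163). No list passed by camera, by camera with an estimated correlation (smallest adjusted p = 0.933) or by fry. MYC targets (median -0.12, camera adjusted p = 0.149) and granulocyte and erythroid genes (median 0.74, camera adjusted p = 0.149) came nearest. B cell receptor signalling had median 0.29, camera adjusted p = 0.280, plasma cell genes median 0.33, camera adjusted p = 0.280 and interferon response median -0.32, camera adjusted p = 0.377. Median and mean had opposite signs for marginal zone, B1 and memory genes (median -0.02, mean 0.01), genes described as repressed by BCL6 (median -0.03, mean 0.01) and MHC class II (median -0.11, mean 0.01). Among hypermutation and repair genes Rif1 alone passed (median -0.06, camera adjusted p = 0.503).

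The count for MYC/AIDKO against MYC depends on the model, on single arrays and on Xist. A fit on the 2 groups alone and one with mouse number as a block each gave 0 genes. The Gapdh ratio as a covariate and the mean over probe sets each gave 1, and array weights 452. The count was 68 without MYC/AIDKO replicate 3 and 41 without replicate 1. It was 2 without MYC replicate 5 or MYC/AIDKO replicate 5, 4 without MYC replicate 1 and 5 without MYC/AIDKO replicate 2. It was 6 without MYC replicate 2, MYC/BCL6 replicate 2, 5, 9 or 10, or MYC/BCL6/AIDKO replicate 3. The variance share had an exact permutation p of 0.0159 without MYC/AIDKO replicate 1 and 0.0238 without replicate 3. Zdhhc21 alone kept its call whichever array was left out. MYC replicate 5 ended 8 of the 10 calls, among them Ehhadh (adjusted p = 0.0515) and G3bp2 (adjusted p = 0.0687). MYC/AIDKO replicate 5 ended those of G3bp2 (adjusted p = 0.0913) and Cryl1 (adjusted p = 0.0768). Mir1949 lost its call with any of 21 arrays left out (up to adjusted p = 0.152), Eef1akmt1 with 18 (0.179), Rif1 with 14 (0.147) and Tmem39b with 11 (0.118). Atf7ip lost it with any of 4 (0.0913) and Snx6 with any of 3 (0.0913). With Xist level as a covariate, which separates all 5 MYC tumours from 4 of 5 MYC/AIDKO tumours, 29 genes differed.

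The difference between the AIDKO effects was tested itself, and 867 genes passed. Of these, 407 had a more positive effect in the knock-in background and 460 a more negative one. Sdc1 (-6.31 ± 0.89, adjusted p = 0.00111), Zg16 (-6.31 ± 1.77, adjusted p = 0.0302) and Pgam2 (-6.22 ± 1.25, adjusted p = 0.00561) led the latter. Hnrnpll (-5.58 ± 0.97, adjusted p = 0.00240), Dmbt1 (-5.57 ± 1.71, adjusted p = 0.0457), Epcam (-5.54 ± 1.10) and Xbp1 (-3.29 ± 0.58) followed. More positive effects included Spib (5.51 ± 1.07, adjusted p = 0.00446), Cd79a (4.22 ± 1.28, adjusted p = 0.0436) and Cd22 (3.69 ± 0.72, adjusted p = 0.00448). Bank1 (3.96 ± 0.91) and Klf2 (3.64 ± 0.81) were others. Bpifa2 (7.79 ± 2.07, adjusted p = 0.0232), 2310057J18Rik (6.35 ± 1.78), Smr3a (6.24 ± 1.92), Car6 (5.78 ± 1.71) and Wfdc12 (5.67, adjusted p = 0.0227) passed too. Each of these had its highest MYC signal in replicate 1, far above the rest of that group, and they belong to the genes high in few tumours described above. Col4a1 (-1.67, adjusted p = 0.0592) and Pdgfrb (-1.73, adjusted p = 0.0669) did not pass. The difference of Sdc1 combines a value of -4.22 in the knock-in background with a value of 2.09 that did not pass in the other.

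Plasma cell genes were lower in this difference (median -2.01, camera adjusted p = 9.96e-09, adjusted p = 0.149 with an estimated correlation). Among 20 members, 0 differed upward, 10 downward and 10 did not pass (0 and 11 adjusted over the list alone). MHC class II genes were higher in it (median 2.18, camera adjusted p = 4.38e-06, adjusted p = 0.321 with an estimated correlation). Among 14 members, 2 differed upward, 0 downward and 12 did not pass (11 and 0 adjusted over the list alone). Naive B cell genes were higher (median 1.29, camera adjusted p = 2.26e-05, adjusted p = 0.253 with an estimated correlation). Among 16 members, 4 differed upward, 0 downward and 12 did not pass (7 and 0 adjusted over the list alone). B cell receptor signalling genes were higher (median 0.95, camera adjusted p = 5.05e-05, adjusted p = 0.253 with an estimated correlation). Among 22 members, 6 differed upward, 1 downward and 15 did not pass (9 and 1 adjusted over the list alone). Stromal genes were lower (median -1.09, camera adjusted p = 0.000853, adjusted p = 0.467 with an estimated correlation). Among 23 members, 0 differed upward, 0 downward and 23 did not pass (0 and 8 adjusted over the list alone).

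Targets of p53 were lower (median -0.70, camera adjusted p = 0.00290, adjusted p = 0.321 with an estimated correlation). Among 22 members, 0 differed upward, 2 downward and 20 did not pass (0 and 3 adjusted over the list alone). NF-kB response genes were higher (median 0.74, camera adjusted p = 0.0122, adjusted p = 0.722 with an estimated correlation). Among 21 members, 0 differed upward, 0 downward and 21 did not pass (0 and 0 adjusted over the list alone). By fry the NF-kB (adjusted p = 0.255) and stroma lists (0.0863) did not pass. The NF-kB call ended without MYC replicate 4 (adjusted p = 0.0751) or MYC/BCL6/AIDKO replicate 1 (adjusted p = 0.0820). With the admixed-cell scores as covariates 41 genes passed, and p53 targets -0.38 (adjusted p = 0.0524) did not. Without MYC/BCL6 replicate 12, 1539 genes passed. Of 38 named genes, 22 kept their call whichever array was left out. Bach2 lost it with any of 22 arrays left out (up to adjusted p = 0.0882) and Smr3a with any of 19 (0.0870). Dmbt1 did with 18 (0.0854), H2-Ab1 with 17 (0.0927) and Car6 with 8 (0.0849). So did 2310057J18Rik with 5 (0.0641), Zg16 with 4 (0.0595) and Wfdc12 without MYC replicate 1 (0.0512). Among lists that did not pass, median and mean differed in sign for genes described as repressed by BCL6 (median 0.08, mean -0.07) and cell cycle (median 0.02, mean -0.05). They also did for hypermutation and repair (median -0.05, mean 0.06) and follicular dendritic cell genes (median -0.10, mean 0.02).

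Averaged over both backgrounds, 1501 genes differed with loss of AID, 854 higher and 647 lower. The average need not hold in each background, as 10 genes were called without the knock-in and 3357 with it. Mean plasma cell list levels were 8.79 in MYC and 9.13 in MYC/AIDKO, but 11.0 in MYC/BCL6 and 9.39 in MYC/BCL6/AIDKO. The average fall of plasma cell genes given below thus comes from the knock-in background. Fcmr, the IgM Fc receptor gene (3.51 ± 0.66, adjusted p = 0.00237), and the Src-family kinase Blk (3.14 ± 0.59, adjusted p = 0.00248) rose. Gfi1b (2.79 ± 0.70), H2-Ob (2.79 ± 0.53) and Nxpe2 (2.67 ± 0.61) were the other largest rises. Arg1 (-2.87 ± 0.61), Pgam2 (-2.84 ± 0.63), Tnfrsf17 (-2.81 ± 0.43, adjusted p = 0.000859) and Aplnr (-2.46 ± 0.60) fell. B cell receptor signalling genes rose (median 0.77, camera adjusted p = 1.70e-07, adjusted p = 0.171 with an estimated correlation). Among 22 members, 14 rose, 0 fell and 8 did not pass (14 and 0 adjusted over the list alone). MHC class II genes rose (median 1.06, camera adjusted p = 0.000211, adjusted p = 0.506 with an estimated correlation). Among 14 members, 6 rose, 0 fell and 8 did not pass (9 and 0 adjusted over the list alone). Naive B cell genes rose (median 0.66, camera adjusted p = 0.00316, adjusted p = 0.440 with an estimated correlation). Among 16 members, 2 rose, 0 fell and 14 did not pass (3 and 0 adjusted over the list alone). Plasma cell genes fell (median -0.68, camera adjusted p = 0.000310, adjusted p = 0.440 with an estimated correlation). Among 20 members, 0 rose, 6 fell and 14 did not pass (1 and 7 adjusted over the list alone). Stromal genes fell (median -0.47, camera adjusted p = 0.000108, adjusted p = 0.440 with an estimated correlation). Among 23 members, 1 rose, 6 fell and 16 did not pass (1 and 8 adjusted over the list alone). MYC targets fell (median -0.21, camera adjusted p = 7.14e-05, adjusted p = 0.440 with an estimated correlation). Among 30 members, 0 rose, 3 fell and 27 did not pass (0 and 5 adjusted over the list alone).

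NF-kB response genes rose on average (median 0.47, camera adjusted p = 0.0239, adjusted p = 0.665 with an estimated correlation). Among 21 members, 3 rose, 1 fell and 17 did not pass (7 and 1 adjusted over the list alone). T cell genes rose on average (median 0.43, camera adjusted p = 0.0407, adjusted p = 0.665 with an estimated correlation). Among 17 members, 3 rose, 0 fell and 14 did not pass (3 and 0 adjusted over the list alone). Granulocyte and erythroid genes had a higher median, with no member passing and 3 arrays high (MYC/AIDKO replicate 5, MYC/BCL6/AIDKO replicates 4 and 6) (median 0.91, camera adjusted p = 0.0407, adjusted p = 0.703 with an estimated correlation). Among 16 members, 0 rose, 0 fell and 16 did not pass (0 and 0 adjusted over the list alone). The NF-kB call ended without MYC replicate 2 (adjusted p = 0.0632) or 3 (0.0523), MYC/AIDKO replicate 1 (0.0555) or MYC/BCL6/AIDKO replicate 1 (0.0926). That of T cell genes ended without any of 12 arrays (up to 0.120, MYC/BCL6/AIDKO replicate 4). That of granulocyte and erythroid genes ended without any of 9 (up to 0.363, MYC/AIDKO replicate 5). By fry none of these 3 lists passed (adjusted p = 0.190, 0.190 and 0.227). With the admixed-cell scores as covariates 19 genes passed, with the Gapdh ratio 89 and with Xist 860. Of the 9 lists, 3 stayed called with the scores: B cell receptor signalling 0.59 (adjusted p = 0.000266), plasma cell -0.40 (adjusted p = 0.0287) and MYC targets -0.17 (adjusted p = 0.000745). MHC class II had 0.22 (adjusted p = 0.482), naive 0.36 (adjusted p = 0.149), NF-kB 0.29 (adjusted p = 0.172) and granulocyte and erythroid genes 0.58 (adjusted p = 0.198). The scores cannot test T cell and stroma genes. Median and mean differed in sign for genes described as repressed by BCL6 (median 0.07, mean -0.03) and hypermutation and repair (median 0.07, mean -0.03), which did not pass. Nor did myeloid (median 0.04, mean -0.01) and follicular dendritic cell genes (median -0.02, mean 0.12), where they differed as well.

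The average knock-in effect covered 2696 genes, 1568 higher and 1128 lower, or 1142 with the admixed-cell scores as covariates. Bcl6 itself rose by 2.48 (adjusted p = 0.00367). Pgam2 (3.77 ± 0.63), Ell2 (3.76 ± 0.43, adjusted p = 8.07e-06), Tent5c (3.66 ± 0.72), the disulfide isomerase gene Pdia5 (3.42 ± 0.52) and Dsp (3.38 ± 0.55) rose most. Vpreb3 (-4.57 ± 0.55, adjusted p = 9.61e-06), Emid1 (-3.43 ± 0.50), Lgr5 (-3.26 ± 0.46), Cd79a (-3.26 ± 0.64) and Serpinb1a (-3.23 ± 0.47) fell most. Plasma cell genes rose (median 1.45, camera adjusted p = 3.29e-06, adjusted p = 0.215 with an estimated correlation). Among 20 members, 12 rose, 1 fell and 7 did not pass (14 and 1 adjusted over the list alone). Interferon response genes rose (median 0.84, camera adjusted p = 0.000413, adjusted p = 0.543 with an estimated correlation). Among 22 members, 8 rose, 0 fell and 14 did not pass (8 and 0 adjusted over the list alone). Bst2 (1.77 ± 0.40, adjusted p = 0.00215) and Tap1 (1.14 ± 0.25) were among them. Immature B cell genes fell (median -1.69, camera adjusted p = 0.000413, adjusted p = 0.215 with an estimated correlation). Among 16 members, 0 rose, 9 fell and 7 did not pass (1 and 9 adjusted over the list alone). Cell cycle genes fell (median -0.18, camera adjusted p = 0.00207, adjusted p = 0.543 with an estimated correlation). Among 27 members, 0 rose, 7 fell and 20 did not pass (0 and 11 adjusted over the list alone). Kif11 (-0.61 ± 0.15) and Ccne2 (-0.86 ± 0.22) were among them.

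Stromal genes rose with the knock-in on average (median 0.73, camera adjusted p = 0.00194, adjusted p = 0.543 with an estimated correlation). Among 23 members, 4 rose, 0 fell and 19 did not pass (12 and 0 adjusted over the list alone). NF-kB response genes rose too (median 0.44, camera adjusted p = 0.00861, adjusted p = 0.543 with an estimated correlation). Among 21 members, 4 rose, 0 fell and 17 did not pass (4 and 0 adjusted over the list alone). Targets of p53 rose (median 0.45, camera adjusted p = 0.0281, adjusted p = 0.543 with an estimated correlation). Among 22 members, 8 rose, 1 fell and 13 did not pass (8 and 1 adjusted over the list alone). B cell receptor signalling genes fell (median -0.46, camera adjusted p = 0.00727, adjusted p = 0.543 with an estimated correlation). Among 22 members, 1 rose, 8 fell and 13 did not pass (1 and 8 adjusted over the list alone). The p53 call ended without MYC replicate 4 (adjusted p = 0.0569) or MYC/AIDKO replicate 5 (adjusted p = 0.0509). By fry the cell cycle list did not pass (adjusted p = 0.0932). With the admixed-cell scores as covariates these no longer passed: cell cycle -0.14 (adjusted p = 0.122), interferon 0.30 (adjusted p = 0.122), NF-kB 0.12 (adjusted p = 0.341) and p53 targets 0.40 (adjusted p = 0.0907). Stroma genes, in the scores, had 0.07. Germinal centre genes had a positive median and mean (median 0.12, mean 0.12) beside a test that leaned down (camera adjusted p = 0.752).

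Igha, the constant region gene of IgA, was low in every tumour without AID. It was at most 154.2 in all 11 of them, 58.8 to 31516 (median 4574) in MYC/BCL6, and 7687, 81.4, 2401, 74 and 283.2 in MYC replicates 1 to 5. Igha was 29.5-fold lower in MYC/BCL6/AIDKO than in MYC/BCL6 (log2 change -4.88 ± 1.15, adjusted p = 0.00257). It differed by -3.00 ± 1.46, adjusted p = 0.492 between MYC/AIDKO and MYC and by 1.99 ± 1.23, adjusted p = 0.245 between MYC/BCL6 and MYC. Averaged over both backgrounds it was 15.4-fold lower without AID (-3.94 ± 0.93, adjusted p = 0.00823).

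Ighm was low in most MYC/BCL6 tumours alone. Its median there was 713.7, with 27331, 27680, 27067 and 5649.5 in replicates 1, 9, 10 and 12, against at least 7426.5 in every tumour of the other groups. Both genes were low in MYC/BCL6 replicates 3 (Igha 122.4, Ighm 89.5) and 6 (58.8 and 956.7). It was lower in MYC/BCL6 than in MYC (-4.08 ± 1.25, adjusted p = 0.0160) and higher in MYC/BCL6/AIDKO than in MYC/BCL6 (3.96 ± 1.18, adjusted p = 0.0140). The variable genes lie outside the rule for named genes and were chosen after their values were seen. Ighv14-2 was lower in MYC/BCL6 than in MYC (-3.23 ± 0.71, adjusted p = 0.00124) and higher in MYC/BCL6/AIDKO than in MYC/BCL6 (3.49 ± 0.67, adjusted p = 0.000403). Igkv14-111 fell in the first of these (-2.57 ± 0.71, adjusted p = 0.00790) and Igkv8-30 in the second (-1.44 ± 0.43, adjusted p = 0.0149). Of 13 immunoglobulin genes tested, 2 rose and 2 fell with loss of AID in the knock-in tumours. With the knock-in when AID was present 0 rose and 3 fell.

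The knock-in effects with and without AID share no arrays but do share residual variances. There were 18 genes higher in both (7.24 expected by chance, Fisher's exact p = 0.000122), 10 lower in both (1.61 expected, Fisher's exact p = 1.64e-07) and 1 opposite. The log2 changes correlated at 0.249 across 12717 genes. These are not independent replicates, so Fisher's p does not gauge the overlap. This overlap was 332 genes without MYC/BCL6/AIDKO replicate 5 and 2 without replicate 1. The AIDKO effects in the 2 backgrounds shared 1 gene, lower in both (0.870 expected, Fisher's exact p = 0.605), with a correlation of 0.0524 across genes. They shared 17 without MYC/AIDKO replicate 3 and 0 without replicate 5.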

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

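The tests of label swap, of the genotype of MYC/BCL6 replicate 12 and MYC/BCL6/AIDKO replicate 5, and of dilution, RNA degradation and sex as causes of the plasma cell pattern were chosen after the result was seen; the tests of flanking regions and of other splits were planned.

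In groups of 5 and 6, an array was singled out when its gap to the nearest other array, as a share of the group's range, passed Dixon's 95% critical value. MYC/BCL6, with 12 arrays, was not tested. This picked 55 of 429 groups of values, where chance gives about 1 in 20 (21.45), and most of them fall on few arrays. The gap is given in parentheses. MYC/BCL6/AIDKO replicate 5 was highest for the immature and precursor B cell list (0.766), Emid1 (0.762), Vpreb3 (0.698), Hnrnpll (0.657), Tspoap1 (0.645) and Capsl (0.640), and lowest for Bcl6 (0.825), Gzmk (0.765), Shtn1 (0.748), Nxpe2 (0.708), Myc (0.685), Bmyc (0.674), the MHC class II presentation list (0.671), Bcl3 (0.663), the median signal (0.655), Ell2 (0.637), Timd2 (0.634) and Tent5c (0.631). MYC replicate 1 was highest for Smr3a (0.963), Car6 (0.943), Bpifa2 (0.942), Wfdc12 (0.890), Cd4 (0.867), 2310057J18Rik (0.842), Pip (0.837), the germinal centre B cell list (0.770) and the 3' to 5' ratio of Actb (0.727), and lowest for the MYC targets and ribosome biogenesis list (0.799) and Foxp1 (0.751). MYC/AIDKO replicate 1 was highest for the median signal (0.876), Mamdc2 (0.865), Ighv14-2 (0.813), Spag6 (0.782) and the p53 targets list (0.760), and lowest for Cyb561a3 (0.907) and Cd2 (0.890). MYC replicate 4 was highest for Shtn1 (0.943), Ms4a1 (0.936) and Il10 (0.725), and lowest for Trp53inp1 (0.819) and Bach2 (0.815). MYC/AIDKO replicate 3 was highest for the 3' to 5' ratio of Gapdh (0.892) and lowest for Capsl (0.736) and Lgr5 (0.718). MYC/AIDKO replicate 4 was lowest for the MHC class II presentation list (0.835), Klf2 (0.800) and Bmyc (0.712). MYC replicate 5 was highest for Spag6 (0.839) and lowest for Gata1 (0.750). MYC/BCL6/AIDKO replicate 1 was highest for the interferon response list (0.705) and Pgam2 (0.671). MYC/AIDKO replicate 2 was highest for Nme1 (0.731). MYC/AIDKO replicate 5 was highest for Tent5c (0.942). MYC/BCL6/AIDKO replicate 3 was highest for Col4a1 (0.690). MYC/BCL6/AIDKO replicate 6 was highest for Spag6 (0.790).

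The AIDKO effect differed between the backgrounds by a test of the difference itself for 867 genes and 7 lists: plasma cell (-2.01), stroma (-1.09) and p53 targets (-0.70) had a lower median in the knock-in background, and MHC class II (2.18), naive B cell (1.29), B cell receptor signalling (0.95) and NF-kB response (0.74) a higher one. None of the 7 passed with an estimated correlation (smallest adjusted p = 0.149), and 5 passed by fry. The same test picked 59 of the named genes. Their log2 differences were positive for Bpifa2 (7.79), 2310057J18Rik (6.35), Smr3a (6.24), Car6 (5.78), Wfdc12 (5.67), Spib (5.51), Ms4a1 (5.40), Cyb561a3 (4.97), B3gnt5 (4.59), Lsp1 (4.54), Ly6d (4.50), Cd79a (4.22), Bank1 (3.96), Napsa (3.82), Cd22 (3.69), Klf2 (3.64), Itgb7 (3.63), Bach2 (3.38), Serpinb1a (3.36), Timd2 (3.19), Tnfrsf19 (3.12), Clec2i (3.05), H2-Ab1 (2.94), Bmyc (2.86), Trib2 (2.70), Foxp1 (1.85), Cryl1 (1.74), Vav2 (1.59), Eef1akmt1 (1.58), Snx6 (1.46), Mir1949 (1.32) and Zdhhc21 (1.06), and negative for Sdc1 (-6.31), Zg16 (-6.31), Pgam2 (-6.22), Hnrnpll (-5.58), Dmbt1 (-5.57), Epcam (-5.54), Mamdc2 (-5.51), Slpi (-5.13), Gabra4 (-5.02), Nbea (-4.78), Gpm6a (-4.56), Spag6 (-4.56), Ell2 (-3.79), Phlda1 (-3.77), Tnfrsf17 (-3.65), Ccnd2 (-3.42), Trp53inp1 (-3.36), Xbp1 (-3.29), Mgarp (-3.16), Edem1 (-2.56), Prdm1 (-2.43), Phlda3 (-1.57), Ehhadh (-1.49), Blnk (-1.29), Atf7ip (-1.26), Tmem39b (-1.20) and Srm (-1.12).

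The plasma cell pattern of MYC/BCL6 against MYC (plasma cell genes high, B cell genes low) was weighed first. More cells of other types in place of tumour B cells would lower all tumour transcripts and raise other cells' markers alike. The 57 MYC target and cell cycle members moved by a median of -0.027 (median absolute deviation 0.25). All 54 B cell members had a median of -0.96, and markers moved apart (T cell 0.33, myeloid 0.33, granulocyte and erythroid -0.28, stroma 1.28). Dilution is therefore argued against as the whole cause, though the stromal rise itself stays open. RNA degradation is argued against by a plasma cell median of 2.28 with the Actb ratio as a covariate (adjusted p = 1.61e-08), and sex by a median of 2.61 with Xist as a covariate. Quantile normalization in place of the deposited scaling gave 3440 called genes against 3452. A change of state of the tumour cells, the mixed strain background, unrecorded differences between mice and the site or stage of sampled tumours were not tested and stay open.

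Of 4 arrays nearer to another group than to their own, MYC/BCL6 replicate 12 and MYC/BCL6/AIDKO replicate 5 were weighed. A swap between their groups is argued against, since the closest MYC/BCL6/AIDKO array correlated with the MYC/BCL6 mean at 0.894 and the other 11 MYC/BCL6 arrays at no less than 0.950. A wrong AID genotype of replicate 12 is argued against by its Igha signal of 6792, when none of the 11 tumours without AID exceeded 154.2. Replicate 5 may lack the knock-in: its Bcl6 signal of 12.2 lies within the MYC/AIDKO range (11.2 to 42.2), but MYC/BCL6 replicate 5 has 4.7 beside the profile of its own group, so a low Bcl6 signal alone does not settle a genotype. The others, MYC/AIDKO replicates 1 (0.916 with MYC, 0.899 with its own group) and 3 (0.939 and 0.924), were nearer to MYC. Replicate 1 had the highest median signal (85.5), and no explanation was tested for either.

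Genes carried along beside the knock-in could account for calls near it. Only 1.15% of the 2696 genes of the average BCL6 effect lie within 20 Mb of Ighm (1.03% of others, Fisher's exact p = 0.595), which argues against this flanking region as the source of that count.

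Same-size splits of the arrays (100 drawn, the real one included) gave as many called genes only in the real case for MYC/BCL6/AIDKO against MYC/BCL6 (3357, highest other 22), MYC/BCL6 against MYC (3452, highest other 88), the average AIDKO effect (1501, highest other 3) and the average BCL6 effect (2696, highest other 875). The same held for the difference of AIDKO effects (867, highest other 2), split by AID status with additive effects removed. Within 100 splits this argues against chance. For MYC/AIDKO against MYC 6 of 100 splits gave at least 10 genes (highest other 43) and for MYC/BCL6/AIDKO against MYC/AIDKO 6 of 100 gave at least 62 (highest other 382), so chance cannot be excluded. Splits calling several times the real count point to an untested structure of these samples.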

How the results depend on the processing

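Comparisons are named in the order MYC/AIDKO against MYC, MYC/BCL6/AIDKO against MYC/BCL6, MYC/BCL6 against MYC, MYC/BCL6/AIDKO against MYC/AIDKO, difference of AIDKO effects, average AIDKO effect and average BCL6 effect, with 10, 3357, 3452, 62, 867, 1501 and 2696 genes called. The Actb covariate and the joint omission of 3 atypical arrays (MYC/AIDKO replicate 1, MYC/BCL6 replicate 12, MYC/BCL6/AIDKO replicate 5) were chosen after seeing the data; MYC/AIDKO replicate 3, also nearer to another group than to its own, was not among the 3, and leaving it out alone gave 68 genes for MYC/AIDKO against MYC. Quantile normalization gave 8, 3288, 3440, 85, 859, 1366 and 2664 genes, all within 1.5 times, and pseudocount 5.5 and trend and robust variance also kept every count within that range. Changes outside it follow by setting. The cause was not tested, except that all probe sets test more features and that leaving out arrays or groups leaves fewer samples.

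All probe sets gave 266, 6423, 7241, 147, 2231, 2973 and 4920 calls. Array weights gave 452 for the first comparison, 1153 for the fourth and 2176, 2799 and 4297 for the last contrasts. With marker covariates for admixed cells, every contrast after the first moved, to 76, 1490, 5, 41, 19 and 1142. No filter gave 6 for MYC/AIDKO against MYC and 34 for MYC/BCL6/AIDKO against MYC/AIDKO, where the stricter filter gave 116 and pseudocount 22 gave 97, so the level at which signal counts as background bears on the smallest counts. The mean over probe sets gave 1 and leaving out chromosomes 6 and 12 gave 4 for MYC/AIDKO against MYC. Fits on only the 2 groups compared gave 0 for MYC/AIDKO against MYC and 0 for MYC/BCL6/AIDKO against MYC/AIDKO. The Gapdh ratio gave 1 for MYC/AIDKO against MYC, 2226 for MYC/BCL6/AIDKO against MYC/BCL6 and 89 for the average AIDKO effect; the ratio itself was lower in both groups without AID, so loss of AID and RNA quality were not separated. The Actb ratio gave 1971, 392 and 967 for MYC/BCL6/AIDKO against MYC/BCL6, the difference of AIDKO effects and the average AIDKO effect. Xist gave 29, 121 and 860 for MYC/AIDKO against MYC, MYC/BCL6/AIDKO against MYC/AIDKO and the average AIDKO effect. Without the 3 atypical arrays MYC/AIDKO against MYC had 157 genes and 1 list, MYC/BCL6/AIDKO against MYC/AIDKO 1520 genes and the difference of AIDKO effects 1913, the shared calls rose from 1 to 32 (AIDKO effects) and from 28 to 512 (BCL6 effects), and the variance share of MYC/AIDKO against MYC was 20.5% (exact permutation p = 0.0159).

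Mouse numbers recur between groups, so a replicate block was fitted: it gave 0 genes for MYC/AIDKO against MYC and 22 for MYC/BCL6/AIDKO against MYC/AIDKO. Residuals of same-number arrays correlated above 0.1 in 2 of 31 pairs, so the numbers do not pair the mice, and the unblocked fit is the one reported.

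Estimated correlation in camera left 0 lists called in each of the 6 contrasts that had any. By fry 4 of 8, 5 of 7, 6 of 9 and 7 of 8 called lists passed in the last 4 contrasts, and all in MYC/BCL6/AIDKO against MYC/BCL6 and MYC/BCL6 against MYC. Marker covariates gave 4, 3 and 5 called lists for MYC/BCL6/AIDKO against MYC/AIDKO, the average AIDKO effect and the average BCL6 effect, 3 in each being among the 8, 9 and 8 called without them. The variance share of MYC/BCL6/AIDKO against MYC/AIDKO was 15.1% with no filter (exact permutation p = 0.0519).

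Reversed values were, for the differences of Bcl6, MYC/AIDKO against MYC with Xist (-0.47) and the average AIDKO effect with the replicate block (0.023); for those of Myc, MYC/AIDKO against MYC with the Gapdh ratio (-0.17), with Xist (-0.62), without MYC replicate 1 (-0.0059) and without MYC/AIDKO replicate 5 (-0.31, where the highest value with any array left out was 0.44), and MYC/BCL6 against MYC with the Actb ratio (0.078) and without MYC replicate 2 (0.050, where the lowest value with any array left out was -0.29); with means over probe sets, Wdr43 in MYC/BCL6 against MYC (-0.18) and in the average BCL6 effect (-0.075), and Ddx21 in the average BCL6 effect (0.012). With marker covariates Dcn reversed in the average BCL6 effect (-0.023), as did the T cell list in MYC/BCL6/AIDKO against MYC/BCL6 (-0.069) and the average AIDKO effect (-0.18), and the stroma list in MYC/BCL6/AIDKO against MYC/BCL6 (0.16), the difference of AIDKO effects (0.026) and the average AIDKO effect (0.12). The covariates include these lists' own levels.

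Leaving out each array in turn gave 2 to 68, 2847 to 3992, 2826 to 3844, 2 to 847, 625 to 1539, 1053 to 2204 and 2240 to 3248 called genes, and 0 to 3, 8 to 11, 6 to 8, 7 to 10, 6 to 9, 6 to 10 and 7 to 10 called lists (0, 9, 6, 8, 7, 9 and 8 with all arrays). Shared calls ranged from 0 to 17 (AIDKO effects) and 2 to 332 (BCL6 effects), and the variance shares of the first 4 comparisons from 14.7 to 20.5%, 26.0 to 33.9%, 29.8 to 39.1% and 16.1 to 25.4%, the last with exact permutation p from 0.00794 to 0.111. Over all settings, 391 results for named genes gave 17112 values, of which 15695 kept direction and side of the threshold, 1330 no longer passed, 75 newly passed and 12 reversed; 47 list medians gave 1692, of which 1575, 112, 0 and 5.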

Other observations

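The genes of the first 2 paragraphs were chosen after their values were seen, and the test of salivary gland markers after the pattern it weighs was seen, with the markers listed before their own values were examined. Hnrnpll, a splicing regulator, was not high in every tumour of a group that had it high: its signal was 2741, 2145 and 3224 in MYC/AIDKO replicates 2, 4 and 5 but 326.8 and 102.5 in replicates 1 and 3, 1334 to 2731 in MYC/BCL6 replicates 1 to 11 but 174.3 in replicate 12, and 1543 in MYC/BCL6/AIDKO replicate 5 but at most 293.7 in the others. The 5 MYC tumours had 91.1 to 124.8.

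Pip, Car6 and Wfdc12 were high in the same 4 tumours: Pip had 3117 in MYC replicate 1 and 21653, 1650 and 12000 in MYC/BCL6/AIDKO replicates 2, 3 and 4, Car6 3479, 24838, 2299 and 11746, and Wfdc12 1535, 9214, 462.2 and 3979. Zg16 and Dmbt1 were high elsewhere, with 9094 and 8317 in MYC/BCL6 replicate 9 and 881 and 561 in replicate 12.

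Salivary gland tissue beside the sampled nodes may be the source of these genes in the 4 tumours, as a hypothesis tested on the same data. Of 23 other salivary gland markers, 14 were on the array; 0 of these stand in another list, and 4 were above the signal filter in most of the other 24 tumours. Their mean log2 level was 6.47 to 9.20 in the 4 tumours and 5.15 ± 0.25 in the others (highest 5.93), a gap of 0.533. Signals in MYC replicate 1 and MYC/BCL6/AIDKO replicates 2, 3 and 4 were 10485, 126.9, 5046 and 17137 for Amy1 (at most 116.9 in the others), 13.1, 23346, 21.1 and 27.9 for Prol1 (at most 213.2), 380.8, 14733, 258.7 and 918.4 for Dcpp3 (at most 172.3) and 3978.5, 28.3, 1517.6 and 5937 for Cst10 (at most 30.2), so the marker that is high differs between tumours. Klk1 was not higher (139.8 to 300.3, against a median of 332.5 in the others). MYC/BCL6/AIDKO replicate 1, with Bpifa2 at 734.3 and Smr3a at 235.3, had a marker level of 5.22, within that of the others, so the markers do not bear the hypothesis out there. The values of Bpifa2, 2310057J18Rik, Smr3a, Pip, Car6 and Wfdc12 in the comparisons may thus come from tissue in the sample and not from tumour cells. No sort is named that would remove such tissue.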
